A study of Mus musculus with 32 samples.

How the data were processed

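RNA was measured by sequencing of stranded mRNA libraries made from TRIZOL extracts of mouse tumor cells and CD8 T cells, 32 libraries in 4 tables: tumor cells over time (11 libraries), CD8 T cells over time (9), tumor cells of the knockdown set (6) and CD8 T cells of the knockdown set (6). The values in all 4 tables are TPM, read numbers scaled for gene length and for the total of a library, as the authors deposited them. The submitters' processing notes name FastQC, Trim Galore and HISAT2 with the mm10 build and give no versions. The read counter, the gene annotation and the gene lengths behind the TPM values are not stated there. The tables were scaled separately, so tests were made only within a table, and levels set side by side across tables are descriptions.

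Each table had 33681 rows, 1 per gene symbol. In each table, 27 rows carried a date in place of a symbol and were left out, since a date cannot be mapped back to 1 gene; they held at most 0.184% of the TPM of any library. Symbols of the H2, Hba and Hbb families, as the gene lists give them, were mostly not matched to rows, and none of these genes is named. Rows of these families were not left out, so they entered the fits and gene counts. The MHC class I presentation list therefore rests mainly on its other members. Depth was estimated from the steps between TPM values: each value of a gene is a whole multiple of what 1 read is worth in that library, which recovers whole read numbers. On simulated data, 98.1% of 2225 genes had every read number recovered. In the deposited tables, at least 99.8% of the checked values (up to 4000 reads) lay within 0.05 of a whole number. Only genes whose values fell on whole multiples in at least 1 table were checked, so this rate is largely set by that choice. Those genes held 32.4% to 40.4% of the TPM of a library. The read numbers served only to describe depth and counting noise and entered no test. They were not counted from the reads, and an interval or limit from them would cover counting error only. For genes without recovered numbers, library totals used exon lengths of GENCODE M21, which the submitters do not name. The depth figures rest in large part on those lengths.

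Each comparison used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend=TRUE) on log2(TPM + 1), for genes with a TPM of 1 or more in at least 3 libraries of the table. All groups of a table were in 1 fit, and p-values were adjusted by the Benjamini-Hochberg method over the tested genes. An adjusted p under 0.05 is called past the threshold, and "rose", "fell" or "changed" is used only for genes past it. Log2 fold changes are differences of mean log2(TPM + 1), which understate changes of genes with few TPM; SE is the standard error of the moderated fit. On simulated data with 200 changed genes, the test recovered 61%, 73%, 98% and 98% of 2-fold changes (tumor cells and CD8 T cells of weeks 4 against 2, then tumor cells and CD8 T cells of the knockdown set). Of 4-fold changes it recovered 97%, 97%, 100% and 98%, and 6.51%, 3.41%, 2.46% and 2.97% of its calls were false. The simulated noise was independent between genes, without shifts in cell content or scaling, and the changed genes stood well above the filter. These rates need not carry over to the real data. Week was a factor, with week 4 against week 2 as the main contrast of each time course; the labels give no batch and no pairing. Replicates carry numbers, but no label says whether they came from separate animals, so the p-values may measure technical spread in part. In Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 served for tables and checks and matplotlib 3.10.9 for plots.

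The comparisons, the test, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The 37 lists were triacylglycerol synthesis, fatty acid synthesis, fatty acid uptake and oxidation, lipolysis and lipid droplet, cholesterol synthesis, glycolysis, oxidative phosphorylation, MHC class I presentation, MHC class II presentation, interferon response, chemokines, immune checkpoint ligands, cell cycle, extracellular matrix and mesenchymal transition, luminal epithelial, milk and secretory differentiation, basal and myoepithelial, hypoxia, unfolded protein response, oxidative stress, immediate early and dissociation, cytosolic ribosomal proteins, T cell exhaustion, T cell effector and cytotoxic, naive and memory T cell, T cell identity, CD4 and regulatory T cell, NK cell, B and plasma cell, macrophage and monocyte, neutrophil, dendritic cell, fibroblast, endothelial, adipocyte, skeletal muscle and erythroid. They came from textbook knowledge, and some members stand in several lists. A list with at least 5 tested members was tested with camera of limma at its preset inter-gene correlation of 0.01, which asks whether its members rank higher or lower than all other tested genes. List p-values were adjusted over the lists of a comparison. The test was repeated with a correlation estimated per list. MHC class II presentation and erythroid had too few tested members in each comparison. Unmatched symbols may have a part in this, so the expression of these 2 lists was not assessed.

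Named genes are Mogat1 and 10 focus genes per cell type, the 8 largest rises and falls of each main comparison (4 for the other week contrasts) among genes past the threshold with at least 5 TPM in the higher group and no overlap between the groups, and the members with the smallest p of each list (4 where the list passed, otherwise 2). Unnamed or predicted genes, antigen receptor segments, mitochondrially encoded genes and pseudogenes were not taken. Where fewer than 4 genes passed in a direction, genes with the smallest unadjusted p filled the place and are given as not past the threshold. Reads may be shared within families of near-identical genes, and the counter's handling of such reads is not stated, so single members of the Prl2c, Hspa1, Snord14 and Gzmd to Gzmg families carry that limit.

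Alternatives were pseudocounts of 0.1 and 5, no filter, a filter of 5 TPM, median-of-ratios rescaling, quantile normalization, eBayes without trend, array weights, a 2-fold minimum, replicate number as a block, only the libraries of the 2 weeks compared, and leaving out each library in turn. For lists, fry of limma and the block were run as well. Restricting each test to genes with a lower mean TPM in the table of the other cell type was chosen after seeing the data. Gene positions are from GENCODE M21 on GRCm38, matched by symbol. The share of tumor RNA in a CD8 T cell library was estimated from 4 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d, Uty) as the median of their levels relative to the tumor libraries of the same week or arm; it compares separately scaled tables and assumes that the T cells lack these genes.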

Results

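RNA was sequenced from mouse tumor cells and from CD8 T cells, the lymphocytes that can kill tumor cells. The labels give the tumor cells as MMTV-PyMT breast cancer cells, from the mouse model in which a viral oncogene drives mammary tumors. Over the time course, tumor cells were sampled at week 2 (n = 3), week 3 (n = 4) and week 4 (n = 4) and CD8 T cells at weeks 2, 3 and 4 (n = 3 each). The knockdown set held tumor cells and CD8 T cells labelled shCTRL (a control hairpin RNA, n = 3 each) or shMogat1 (a hairpin RNA against Mogat1, n = 3 each), from xenografts. Estimated depth was 25.1 to 41.2 megareads per library for tumor cells and 27.0 to 44.8 for CD8 T cells over time. In the knockdown set it was 31.8 to 47.9 and 30.8 to 41.7 megareads. Between 11829 and 14184 genes reached 1 TPM per library, and mitochondrially encoded genes took 6.37% to 16.1% of TPM in the tumor time course (highest in week 4 replicate 3), 3.56% to 7.09% in its CD8 T cells, and 3.22% to 5.41% in the knockdown set. Values are means ± SD in TPM over the libraries of a group with the n given here.

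Mogat1 encodes monoacylglycerol acyltransferase 1, which makes diacylglycerol, a precursor of triacylglycerol (ENSMUSG00000012187.13, protein coding, GRCm38 chromosome 1, 78510991 to 78538173). In tumor cells over time, which the series compares as early, middle and late stages, Mogat1 rose at each step, from 2.28 ± 1.45 TPM at week 2 (n = 3) to 6.82 ± 2.17 at week 3 (n = 4) and 37.1 ± 1.75 at week 4 (n = 4). The log2 fold change was 3.63 from week 2 to week 4 (SE 0.28, adjusted p = 9.48e-06). It was 1.31 from week 2 to week 3 (SE 0.28, adjusted p = 0.00834) and 2.33 from week 3 to week 4 (SE 0.26, adjusted p = 0.000371), with no overlap between the libraries of any pair of weeks. Epcam, an adhesion protein of epithelial cells, was at 305.4 ± 70.3, 458.4 ± 57.7 and 528.9 ± 43.5 TPM in the same weeks. In CD8 T cells Mogat1 stayed under the filter on low values, at 0.325 ± 0.152 TPM at week 2, 0.399 ± 0.128 at week 3 and 1.63 ± 1.23 at week 4 (n = 3 each), 3 to 65 reads per library. In the knockdown tumor cells Mogat1 ran against the labels: it was listed at 0 in all 3 shCTRL libraries and at 0.433 ± 0.253 TPM in the libraries labelled shMogat1 (n = 3), which held 12, 2 and 10 reads. The fitted log2 difference of 0.50 (SE 0.18) depends on the pseudocount and is no bound on a fold. Its limma p of 0.0219 was not adjusted because the gene missed the filter, and it was 0.125 without shMogat1 replicate 1, 0.1 without shMogat1 replicate 4 and 0.0503 without shCTRL replicate 1. The knockdown CD8 T cells held 0.433 ± 0.198 TPM in the libraries labelled shMogat1 and 0.235 ± 0.0444 in those labelled shCTRL. A lower Mogat1 level under the label shMogat1 was therefore not seen in either table, and every direction below between these arms is given by the labels as they stand.

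**Figure D1:**
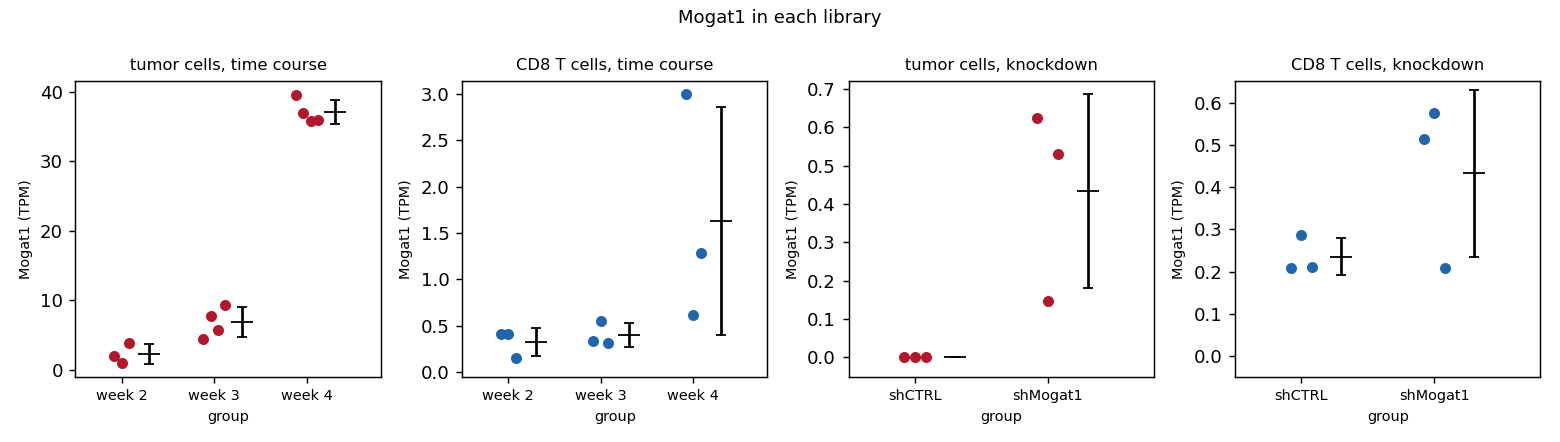
Mogat1 TPM per library in the 4 tables (points, with bars for mean and SD; each panel has its own vertical axis). The 4 tumor libraries of week 4 lie between 35.8 and 39.6 TPM and those of week 2 between 1.02 and 3.87 TPM, while the shCTRL tumor libraries lie at 0.

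Tumor cells of week 4 against week 2 address what changed between early and late tumors. Interferon-induced genes fell together: Cxcl10, a chemokine that draws T cells, went from 723.5 ± 172 (n = 3) to 85.5 ± 28.7 TPM (n = 4; log2 fold change -3.10, SE 0.30, adjusted p = 2.58e-05). Usp18, which restrains interferon signalling, went from 64.8 ± 30.8 to 3.91 ± 0.363 (log2 -3.60, adjusted p = 1.31e-05). Genes of fatty acid synthesis rose, among them Scd1, the desaturase that makes oleic acid, from 87.4 ± 21.1 to 451.9 ± 42.2 TPM (log2 2.38, SE 0.15, adjusted p = 3.94e-06). Srebf1, a transcription factor that drives lipid synthesis genes, rose from 123.7 ± 43.7 to 605.2 ± 58.8 (log2 2.33, adjusted p = 1.93e-05). Among the largest rises were Gfap, an intermediate filament protein best known from astrocytes (0.439 ± 0.0244 to 21.9 ± 9.67 TPM, log2 3.91), and Ccl20, a chemokine (18.2 ± 12.4 to 184.4 ± 54.9, log2 3.41). Others were the transcription factors Zfp750 (log2 3.36) and Sox2 (3.28 ± 1.08 to 39.8 ± 8.95, log2 3.26) and the kinase Stk32b (log2 3.29). The largest falls were in Il1rl1, the interleukin 33 receptor (344.0 ± 166 to 1.73 ± 1.04 TPM, log2 -6.90). Next came Dynap (log2 -6.58), Prl2c2 of the proliferin family (log2 -6.37), the natriuretic peptide gene Nppb (log2 -5.23), the water channel Aqp1 (log2 -5.20) and S100a4, a calcium-binding protein linked to motile cells (1228 ± 577 to 31.3 ± 4.67, log2 -5.15). Prl2c3 was listed at 0 in all 4 week 4 libraries and at 49.3 ± 28.3 TPM at week 2.

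By list, 18 of 22 tested fatty acid synthesis genes rose and 2 fell (21 changed adjusted over the list alone, camera adjusted p = 8.00e-05). Of glycolysis genes, 12 of 22 rose with 0 falling (12 adjusted over the list alone, adjusted p = 0.00095), such as Pfkl (log2 1.48) and Aldoc (log2 1.51). Of 19 hypoxia genes 14 rose and 1 fell (15 adjusted over the list alone, adjusted p = 0.000254), with Ddit4, an inhibitor of the growth kinase mTORC1, at log2 1.88. Of 24 luminal epithelial genes 16 rose and 2 fell (19 adjusted over the list alone, adjusted p = 0.00273): the progenitor markers Kit (log2 2.42) and Elf5 (log2 1.97) rose, and the growth factor Areg fell (log2 -3.59). Epcam rose (log2 0.81, adjusted p = 0.00136). Each of these 4 lists had adjusted p = 0.481 with an estimated correlation. Other genes of lipid handling moved apart: Plin2, a lipid droplet coat protein, rose (69.5 ± 9.80 to 109.0 ± 18.6 TPM, log2 0.63, adjusted p = 0.00442). Cd36, a fatty acid transporter, fell (30.4 ± 9.61 to 6.15 ± 4.01, log2 -2.28, adjusted p = 0.00362, but 0.0789 with array weights, in a range from 0.00143). The acyltransferases that make triacylglycerol were at log2 -0.03 for Dgat1 (adjusted p = 0.912) and 0.02 for Dgat2 (adjusted p = 0.963), and the mitochondrial fatty acid importer Cpt1a at log2 -0.00 (adjusted p = 0.998).

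Of 34 interferon response genes 33 fell and 0 rose (33 adjusted over the list alone, adjusted p = 1.32e-18). Of MHC class I presentation genes, 8 of 14 fell and 0 rose (9 adjusted over the list alone, adjusted p = 0.000126), including B2m, the invariant chain of class I (log2 -1.53, adjusted p = 4.69e-05), and the proteasome subunit Psmb10 (log2 -1.85). Immune checkpoint ligands fell in 9 of 18 genes and rose in 3 (12 adjusted over the list alone, adjusted p = 0.00134): Cd274, which encodes PD-L1, went from 52.8 ± 5.30 to 11.4 ± 6.30 TPM (log2 -2.25, adjusted p = 0.000273). Nt5e, which makes adenosine, fell by log2 2.58. Chemokines fell in 7 of 25 and rose in 2 (9 adjusted over the list alone, adjusted p = 0.00722). These 4 lists also had adjusted p = 0.481 with an estimated correlation. Markers of immune and vessel cells fell in the same libraries. T cell identity genes fell in 14 of 16 and rose in 0 (15 adjusted over the list alone, adjusted p = 6.83e-06), with Cd8a at log2 -2.51. B and plasma cell genes fell in 10 of 12 (10 adjusted over the list alone, adjusted p = 0.000126), with Cd79a at log2 -3.22. Endothelial genes fell in 10 of 16 and rose in 1 (11 adjusted over the list alone, adjusted p = 0.000143), with Cdh5 at log2 -3.04 and Pecam1 at log2 -2.08. The same held for these 3 lists (adjusted p = 0.481 with an estimated correlation). Ptprc, carried by nearly all leukocytes, averaged 55.9 ± 37.3 TPM at week 2, with 98.1 in replicate 1 against 27.4 and 42.2. It averaged 12.1 ± 7.68 at week 4.

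The remaining lists can be summed up by direction. T cell effector and cytotoxic (13 of 23 fell, 2 rose, 16 adjusted over the list alone, adjusted p = 0.000203) and T cell exhaustion (12 of 24 fell, 4 rose, 17 alone, 0.000926) ranked below the other genes. So did naive and memory T cell (11 of 24 fell, 1 rose, 14 alone, 0.00243), NK cell (4 of 10 fell, 4 alone, 0.00364), dendritic cell (5 of 12 fell, 5 alone, 0.00704), macrophage and monocyte (3 of 20 fell, 1 alone, 0.0117) and CD4 and regulatory T cell (5 of 7 fell, 1 rose, 6 alone, 0.0178). Tnf, which stands in the effector list, went the other way (66.7 ± 15.0 to 380.8 ± 61.3 TPM, log2 2.51, adjusted p = 2.77e-05). Cytosolic ribosomal proteins (8 of 43 fell, 3 rose, 2 alone, 0.0188) and oxidative phosphorylation (7 of 37 fell, 2 rose, 5 alone, 0.0497, but 0.0901 with replicate number as a block) also ranked below. Their balance depended on scaling: 12 and 10 fell with 0 rising after median-of-ratios rescaling, and 6 of each direction and 4 of each after quantile normalization, with medians of -0.02 in both. With an estimated correlation these lists had adjusted p = 0.481 (effector, exhaustion, NK, CD4), 0.528 (dendritic), 0.607 (naive and memory), 0.69 (macrophage, oxidative phosphorylation) and 0.739 (ribosomal). Lists that did not pass were skeletal muscle (adjusted p = 0.115, 1 of 7 fell), extracellular matrix and mesenchymal transition (0.129, 6 of 28 fell, 3 rose), milk and secretory differentiation (0.142, 8 of 16 rose) and cholesterol synthesis (0.173, 9 of 23 rose, 1 fell). Others were basal and myoepithelial (0.226, 5 of 12 fell, 3 rose), fatty acid uptake and oxidation (0.238, 11 of 27 rose, 4 fell) and lipolysis and lipid droplet (0.303, 6 of 13 rose, 4 fell). Further lists short of the threshold were oxidative stress (0.299, 7 of 19 fell, 5 rose), immediate early and dissociation (0.362, 6 of 25 fell, 4 rose) and neutrophil (0.362, 3 of 6 rose). The rest were unfolded protein response (0.369, 5 of 19 fell, 4 rose), triacylglycerol synthesis (0.407, 8 of 16 rose, 4 fell), fibroblast (0.408, 2 of 18 fell, 1 rose), adipocyte (0.543, 3 of 7 rose, 1 fell) and cell cycle (0.543, 4 of 35 fell, 3 rose). Mki67, a marker of dividing cells, was at log2 0.18 (adjusted p = 0.246). Median, mean and test differed in sign for cell cycle and fibroblast (median 0.05 in both, test down), unfolded protein response (median -0.14, mean 0.05) and oxidative stress (median 0.03, mean -0.22). Medians turned with rescaling for cell cycle (-0.09 under either), oxidative stress (-0.12 with median-of-ratios, -0.03 with quantile), fibroblast (-0.10 with median-of-ratios) and immediate early and dissociation (from -0.01 to 0.11 with quantile).

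Of 14770 tested genes, 6843 passed the threshold, 4318 higher and 2525 lower at week 4, and 2260 of them changed at least 2-fold. The median of all genes was 0.11 above 0 as deposited and at -0.02 after median-of-ratios rescaling, which evened the directions to 3471 higher and 3482 lower, so the split between rises and falls is relative to that shift.

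**Figure D2:**
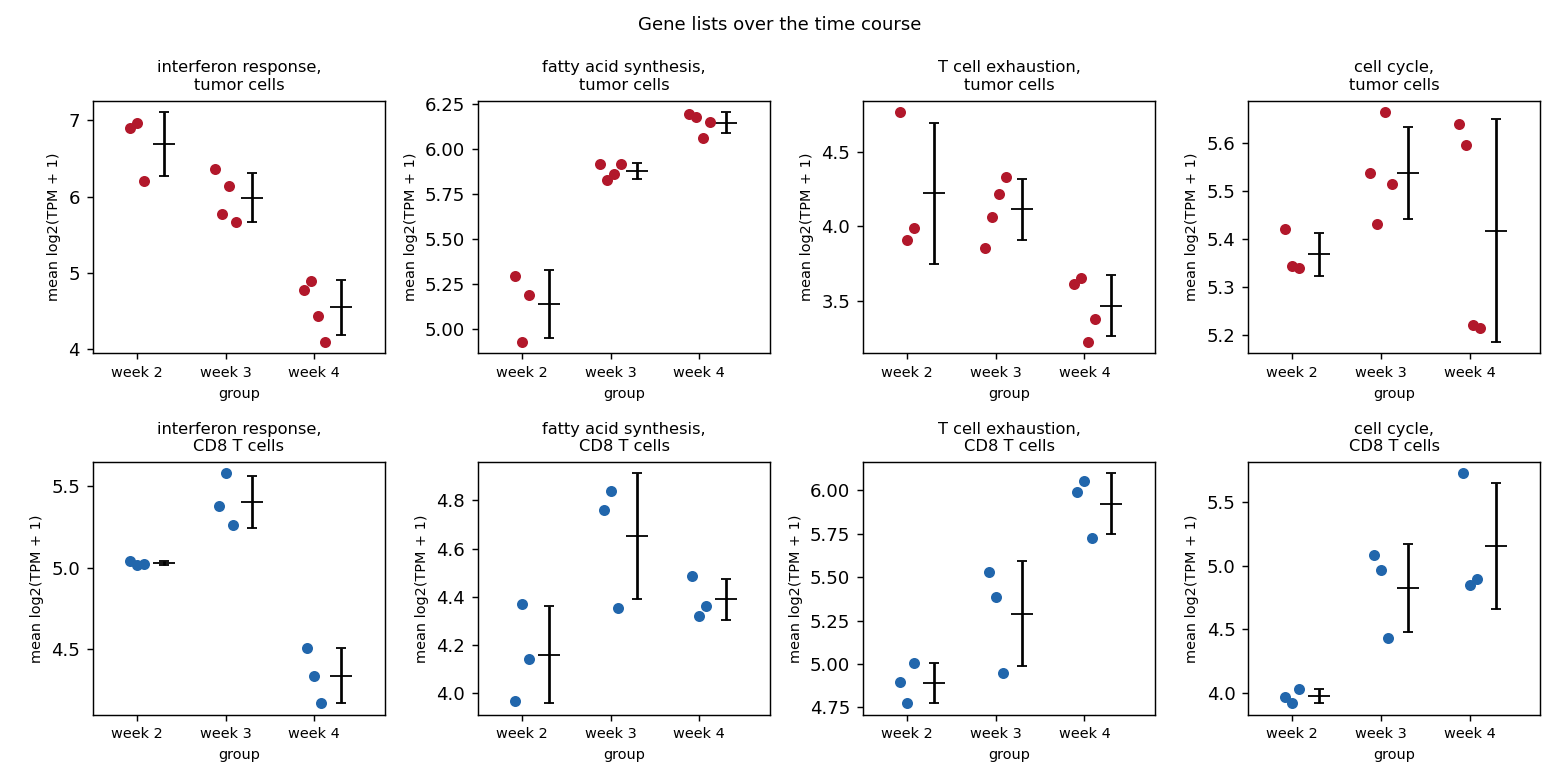
Mean log2(TPM + 1) of the interferon response, fatty acid synthesis, T cell exhaustion and cell cycle lists per library at weeks 2, 3 and 4, tumor cells above and CD8 T cells beneath (points, with bars for mean and SD; axes differ between panels and do not start at 0). In tumor cells the interferon list averaged 6.69 at week 2 and 4.55 at week 4, and in CD8 T cells exhaustion averaged 4.89 and 5.92.

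Between weeks 2 and 3, tumor cells gained transcripts of lipid and sterol synthesis. Scd2, a desaturase, rose from 120.7 ± 39.0 (n = 3) to 297.9 ± 11.2 TPM (n = 4; log2 1.34, SE 0.17, adjusted p = 0.000719), and Dhcr7, which makes cholesterol from its last precursor, rose by log2 1.11 (adjusted p = 0.00109). The largest rises were in Fmod, a collagen-binding proteoglycan (log2 2.19), the acute phase gene Saa2 (log2 2.05), Nptx1 (log2 1.99) and the small nucleolar RNA gene Snord14d (log2 1.98). Among the largest falls were the mast cell protease genes Mcpt4 (log2 -3.18, adjusted p = 0.00103) and Cma1 (log2 -2.70, adjusted p = 0.000457) and Prl2c2 (log2 -2.80). Mast cell genes were not tested as a list. Fatty acid synthesis rose in 15 of 22 genes (17 changed adjusted over the list alone, camera adjusted p = 1.18e-05) and cholesterol synthesis in 14 of 23 (15 adjusted over the list alone, adjusted p = 0.00067). Glycolysis rose in 15 of 22 (16 adjusted over the list alone, adjusted p = 0.000291) and hypoxia in 13 of 19 (15 adjusted over the list alone, adjusted p = 5.96e-05), with 0 falling in each of these 4. Luminal epithelial genes rose in 13 of 24 and fell in 1 (19 adjusted over the list alone, adjusted p = 0.00111), among them the epithelial splicing factor Esrp1 (log2 1.18). Interferon response genes fell in 10 of 34 and rose in 0 (16 adjusted over the list alone, adjusted p = 1.05e-10). All 6 lists had adjusted p = 0.661 with an estimated correlation. These counts moved with median-of-ratios rescaling: 12 fatty acid synthesis genes rose and 1 fell, 7 cholesterol and 8 glycolysis genes rose with 0 falling, 8 hypoxia and 8 luminal genes rose with 1 falling in each, and 18 interferon genes fell. Beside them, T cell identity and B and plasma cell markers ranked lower (adjusted p = 1.18e-05 and 5.96e-05, and 0.661 for both with an estimated correlation), with 0 of 16 and 0 of 12 members past the threshold, also adjusted over the list alone. With median-of-ratios rescaling 2 and 3 of them fell, and with quantile normalization 4 and 3. In all 19 lists passed. For those not named so far, the values are the members past the threshold, the count adjusted over the list alone, the adjusted p and the adjusted p with an estimated correlation. Oxidative phosphorylation (1 of 37 rose, 1 fell, 1 alone, 0.00904, 0.717), MHC class I presentation (1 of 14 fell, 1 alone, 0.0455, 0.813) and chemokines (1 of 25 rose, 1 fell, 2 alone, 0.00615, 0.661) ranked lower. Cytosolic ribosomal proteins (3 of 43 fell, 0 alone, 3.48e-09, 0.681), T cell effector and cytotoxic (3 of 23 fell, 1 rose, 4 alone, 0.00615, 0.717) and naive and memory T cell (2 of 24 rose, 1 fell, 1 alone, 0.0436, 0.843) ranked lower too. CD4 and regulatory T cell (1 of 7 rose, 1 alone, 0.0249, 0.681), NK cell (1 of 10 fell, 1 alone, 0.0277, 0.661) and macrophage and monocyte (0 of 20 past the threshold, 0 alone, 0.0488, 0.843) ranked lower too. Dendritic cell (2 of 12 fell, 3 alone, 0.00904, 0.692) and fibroblast (3 of 18 fell, 1 rose, 3 alone, 0.0349, 0.843) ranked lower too. The call of MHC class I presentation ended with replicate number as a block (0.231). With median-of-ratios rescaling 7 chemokine genes fell and 1 rose, and 2 of each of the naive and memory, CD4 and regulatory T cell and oxidative phosphorylation lists fell with 1, 1 and 0 rising. Cxcl10 (log2 -0.76, adjusted p = 0.0876), Cd274 (log2 -0.67, adjusted p = 0.15) and Cd36 (log2 -1.44, adjusted p = 0.0577) did not pass. Cxcl10 passed without week 3 replicate 1 (0.0495, range 0.0386 to 0.335) and Cd36 without week 3 replicate 4 (0.0373, range 0.0262 to 0.357). Cd274 passed in a fit of these 2 weeks only (0.0353, range up to 0.499), and both rescalings gave a call for Cd36 and median-of-ratios rescaling for Cxcl10. B2m (log2 -0.72, adjusted p = 0.0116) and Epcam (log2 0.60, adjusted p = 0.0165) passed, but not without week 2 replicate 2 (0.062 and 0.0848). Over all alternatives p ran from 0.00241 to 0.401 and from 0.00323 to 0.0952. Of 14770 genes 3560 passed, 2967 higher and 593 lower at week 3, against a shift of the median of all genes of 0.14 that fell to -0.02 after median-of-ratios rescaling (1907 higher, 1444 lower). The count was 5751 without week 2 replicate 1, 1371 without week 2 replicate 2, 2275 without week 3 replicate 3 and 2259 without week 3 replicate 4.

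Between weeks 3 and 4, interferon response genes fell in tumor cells: 31 of 34 fell and 0 rose (32 adjusted over the list alone, camera adjusted p = 2.56e-19), with Usp18 at log2 -2.40 and Cxcl10 falling from 433.2 ± 136 to 85.5 ± 28.7 TPM (n = 4 each; log2 -2.34, adjusted p = 0.000473). MHC class I presentation fell in 7 of 14 genes (9 adjusted over the list alone, adjusted p = 9.24e-06), B2m by log2 0.81 (adjusted p = 0.00595, but 0.061 with no filter, in a range from 0.00062). Checkpoint ligands fell in 8 of 18 (10 adjusted over the list alone, adjusted p = 5.76e-05), Cd274 by log2 1.58 (adjusted p = 0.00606) and Nt5e by log2 2.53. Endothelial genes fell in 12 of 16 (14 adjusted over the list alone, adjusted p = 4.73e-09), with the vessel cadherin Cdh5 at log2 -3.29. All 4 lists had adjusted p = 0.554 with an estimated correlation. Markers of T cells ranked lower in the same libraries: T cell identity (3 of 16 fell, 7 adjusted over the list alone, adjusted p = 0.00177, and 0.636 with an estimated correlation) and T cell exhaustion (11 of 24 fell, 1 rose, 13 adjusted over the list alone, adjusted p = 0.000124, and 0.554 with an estimated correlation). Cd8a was at 7.18 ± 3.56 and 1.64 ± 1.27 TPM and Ptprc, whose libraries overlapped between the weeks, at 25.9 ± 12.3 and 12.1 ± 7.68, both chosen after their values were seen. The effector, naive and memory, NK and B and plasma cell lists also ranked lower (adjusted p = 0.00356, 0.0049, 0.0174 and 0.0209). With an estimated correlation these had 0.636, 0.636, 0.554 and 0.636. Of their members 4 of 23, 6 of 24, 2 of 10 and 1 of 12 fell (8, 6, 2 and 1 changed adjusted over the list alone). The basal keratin Krt5 fell from 21.9 ± 1.35 to 1.07 ± 0.106 TPM (log2 -3.47, SE 0.10, adjusted p = 1.17e-08). The largest falls were in Dynap (log2 -5.33), Il1rl1 (log2 -5.06), Grem1, an inhibitor of bone morphogenetic proteins (log2 -4.65), and Aqp1 (log2 -4.30). Gfap (log2 3.28), Ccl20 (log2 2.55) and Krt23 (log2 2.39) were among the largest rises. Milk and secretory differentiation rose in 4 of 16 genes (6 adjusted over the list alone, adjusted p = 0.00177, and 0.223 with an estimated correlation), including Btn1a1, a milk fat globule protein (log2 1.49), and the iron-sequestering Lcn2 (3392 ± 488 to 6999 ± 309 TPM). In all 17 lists passed. For those not named so far, the values are the members past the threshold, the count adjusted over the list alone, the adjusted p and the adjusted p with an estimated correlation. Fatty acid synthesis (6 of 22 rose, 1 fell, 10 alone, 0.00324, 0.554), luminal epithelial (6 of 24 rose, 1 fell, 11 alone, 0.0315, 0.636) and cytosolic ribosomal proteins (5 of 43 rose, 2 alone, 0.0113, 0.705) ranked higher. Of ribosomal genes, 2 rose with median-of-ratios rescaling and 6 with quantile normalization. Extracellular matrix and mesenchymal transition (5 of 28 fell, 6 alone, 0.0113, 0.648), basal and myoepithelial (4 of 12 fell, 1 rose, 6 alone, 0.026, 0.554) and immediate early and dissociation (7 of 25 fell, 1 rose, 12 alone, 0.00249, 0.636) ranked lower. Plin2 rose here (log2 0.65, adjusted p = 0.00899), as did Scd1 (182.8 ± 17.2 to 451.9 ± 42.2 TPM, adjusted p = 0.000287). Of 14770 genes 2026 passed, 817 higher and 1209 lower at week 4, and the share of higher genes went from 40.3% to 46.0% (median-of-ratios) and 51.5% (quantile). The count was 3580 without week 2 replicate 1, 1251 without week 3 replicate 3, 1289 without week 4 replicate 3 and 1294 without week 4 replicate 4.

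CD8 T cells of week 4 against week 2 address how the T cells changed as tumors grew. Pdcd1, which encodes the inhibitory receptor PD-1, went from 113.2 ± 40.2 to 536.5 ± 77.5 TPM (n = 3 each; log2 2.29, SE 0.28, adjusted p = 0.00248). The cytotoxic protease Gzmb went from 161.2 ± 121 to 1316 ± 609 (log2 3.17, SE 0.52, adjusted p = 0.00633) and the cytokine Ifng from 48.2 ± 27.7 to 271.1 ± 103 (log2 2.54, SE 0.39, adjusted p = 0.00504). Mki67 rose from 23.7 ± 2.94 to 101.3 ± 45.4 TPM (log2 1.97, adjusted p = 0.00401), and Cd8a from 727.8 ± 51.5 to 1099 ± 91.9 (log2 0.59, adjusted p = 0.01). Among the largest rises were the receptor gene Klra5 (log2 4.36), Xcl1, a chemokine that draws dendritic cells (log2 3.70), Mir6386 (log2 3.58), Sema6d (log2 3.39) and Il17a, the interleukin 17 gene (log2 3.38). Among the largest falls were Tdrp (log2 -2.33), Fam101b (log2 -2.20) and Txnip, which restrains glucose uptake (log2 -2.16, adjusted p = 0.0035).

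T cell exhaustion genes rose in 14 of 26 and fell in 0 (17 adjusted over the list alone, camera adjusted p = 9.72e-09), such as the inhibitory receptor Tigit (log2 1.62), the nuclear receptor Nr4a2 (log2 1.37) and Bhlhe40 (log2 1.71). T cell effector and cytotoxic genes rose in 17 of 26 (20 adjusted over the list alone, adjusted p = 3.06e-08), with Tnf at log2 2.07 and the receptor Klrc1 at log2 2.17. Naive and memory T cell genes fell in 12 of 24 and rose in 2 (19 adjusted over the list alone, adjusted p = 0.000121): the costimulatory receptor Cd27 fell (log2 -1.29), while Xcl1 and the survival gene Bcl2 (log2 1.26) rose. Cell cycle genes rose in 22 of 35 (30 adjusted over the list alone, adjusted p = 1.21e-12), with Cenpe at log2 1.86. Interferon response genes fell in 18 of 34 and rose in 0 (23 adjusted over the list alone, adjusted p = 1.62e-11), with the interferon-gamma induced GTPases Igtp (log2 -1.36) and Irgm1 (log2 -1.07). NK cell genes rose in 7 of 13 (8 adjusted over the list alone, adjusted p = 0.000437), including Klri2 (log2 2.46). All 6 lists had adjusted p = 0.511 with an estimated correlation. Havcr2 (14.1 ± 6.45 to 16.2 ± 6.25 TPM, adjusted p = 0.678), Lag3 (29.2 ± 8.23 to 61.2 ± 16.7, adjusted p = 0.0689) and the pore-forming Prf1 (57.5 ± 15.9 to 36.7 ± 7.96, adjusted p = 0.087) did not pass. Lag3 passed without week 3 replicate 4 (0.0302) or week 4 replicate 4 (0.0419), in a range of 0.0131 to 0.199. Prf1 passed without week 2 replicate 3 (0.0167), in a range of 0.00299 to 0.259. Tox, a transcription factor of exhausted cells, rose (log2 1.02, adjusted p = 0.0157), though not without week 4 replicate 3 (0.057, the highest of its alternatives, which ran from 0.000919). Tcf7, a transcription factor of naive and memory cells, was at 1046 ± 358 and 380.3 ± 225 TPM (log2 -1.63, adjusted p = 0.047). This call ended without week 2 replicate 1 (0.131) or 2 (0.142), without week 3 replicate 1 (0.0668), 3 (0.0676) or 4 (0.0662) and without week 4 replicate 2 or 3 (0.07 for each). The range was 0.00285 to 0.142 over all alternatives.

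Oxidative phosphorylation (3 of 37 rose, 3 adjusted over the list alone, adjusted p = 0.000434) and hypoxia (6 of 19 rose, 6 adjusted over the list alone, adjusted p = 0.0173) also ranked higher, at 0.669 and 0.511 with an estimated correlation, and Ddit4 rose by log2 1.89. Markers of other cells moved as well. Luminal epithelial genes rose in 3 of 22 and fell in 1 (10 adjusted over the list alone, adjusted p = 0.0126, and 0.558 with an estimated correlation). Cdh1, an epithelial cadherin that some T cells also make, rose by log2 2.14, and Epcam ran from 12.6 to 30.0 TPM at week 2 and from 29.5 to 38.5 at week 4. The tumor RNA share estimated from Y-linked genes was 1.69% ± 1.51, 5.77% ± 1.71 and 6.38% ± 3.79 at weeks 2, 3 and 4 (n = 3 each), and 10.6% in week 4 replicate 2. B and plasma cell markers ranked lower with 0 of 12 past the threshold, also adjusted over the list alone (adjusted p = 0.0169, and 0.711 with an estimated correlation). In all 19 lists passed. For those not named so far, the values are the members past the threshold, the count adjusted over the list alone, the adjusted p and the adjusted p with an estimated correlation. Cholesterol synthesis (4 of 23 rose, 4 alone, 0.0138, 0.706), glycolysis (6 of 22 rose, 1 fell, 11 alone, 0.0325, 0.669) and oxidative stress (2 of 19 rose, 2 alone, 0.0373, 0.511) ranked higher. CD4 and regulatory T cell (5 of 11 rose, 1 fell, 6 alone, 0.0261, 0.511), macrophage and monocyte (1 of 19 rose, 1 alone, 0.0263, 0.722) and neutrophil (2 of 6 rose, 3 alone, 0.0138, 0.511) ranked higher too. Cytosolic ribosomal proteins (6 of 43 fell, 5 alone, 0.000639, 0.722), fibroblast (1 of 17 rose, 1 alone, 0.0325, 0.722) and endothelial (3 of 13 fell, 4 alone, 0.000847, 0.511) ranked lower. The call of oxidative stress ended with replicate number as a block (0.099). Of ribosomal genes, 1 fell with median-of-ratios rescaling and 6 with quantile normalization, and 4 oxidative stress genes rose with either. The medians were 1.28 for neutrophil, 0.84 for macrophage and monocyte, -1.63 for fibroblast and -0.88 for endothelial. Of 13350 genes 2335 passed, 1377 higher and 958 lower at week 4 (1300 and 1416 with quantile normalization), and 974 changed at least 2-fold. The count was 950 without week 2 replicate 1, 928 without week 2 replicate 2, 1103 without week 4 replicate 2 and 1161 without week 4 replicate 3. It was 1422 with replicate number as a block.

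Between weeks 2 and 3, 6 genes of 13350 passed in CD8 T cells, all higher, and 1825 had an unadjusted limma p under 0.05. Hspa1a and Hspa1b, near-identical heat shock chaperone genes, rose from 64.8 ± 17.8 to 513.5 ± 114 and from 164.5 ± 40.3 to 1259 ± 318 TPM (n = 3 each; log2 2.98 and 2.93, adjusted p = 0.000874 for both). The small nucleolar RNA genes Snord14c and Snord14d rose by log2 2.21 and 2.25 (adjusted p = 0.00141 for both). The other genes past the threshold were Snord14e, which lies outside the rule for named genes and was chosen after its values were seen, and Ddit4. Ddit4 rose by log2 1.48 (adjusted p = 0.0205). Its call ended without week 2 replicate 1 (0.0767) or 2 (0.12), without week 3 replicate 1 (0.159) or 3 (0.0995) and without week 4 replicate 2 (0.0548), 3 (0.0637) or 4 (0.0693), in a range of 0.00256 to 0.198 over all alternatives. Slfn2, Rhebl1, Snx20 and Pja1 had the smallest p among lower genes and did not pass (adjusted p = 0.199 for Slfn2 and 0.234 for the others). Gzmb (log2 2.14, adjusted p = 0.239), Ifng (log2 1.14, adjusted p = 0.259), Mki67 (log2 1.34, adjusted p = 0.234) and Pdcd1 (log2 0.41, adjusted p = 0.566) did not pass either. Of these 8 genes all but Pdcd1 passed with array weights (0.0273 to 0.0323), and the alternatives of those 7 ran up to 0.634. As lists, cell cycle (0 of 35 past the threshold, 19 rose adjusted over the list alone, camera adjusted p = 1.40e-13), interferon response (0 of 34, 0 adjusted over the list alone, adjusted p = 2.54e-05) and luminal epithelial (0 of 22, 10 rose adjusted over the list alone, adjusted p = 1.39e-05) ranked higher, at 0.484 for each with an estimated correlation. In all 18 lists passed. For those not named so far, the values are the members past the threshold, the count adjusted over the list alone, the adjusted p and the adjusted p with an estimated correlation. Fatty acid synthesis (0 of 20 past the threshold, 0 alone, 0.0111, 0.484), cholesterol synthesis (0 of 23 past the threshold, 0 alone, 0.0134, 0.703) and glycolysis (0 of 22 past the threshold, 5 alone, 0.00185, 0.484) ranked higher. Chemokines (0 of 23 past the threshold, 0 alone, 0.00034, 0.638), milk and secretory differentiation (0 of 7 past the threshold, 4 alone, 0.0107, 0.484) and hypoxia (1 of 19 rose, 7 alone, 0.000191, 0.484) ranked higher too. Immediate early and dissociation (2 of 24 rose, 5 alone, 0.0063, 0.66), T cell exhaustion (0 of 26 past the threshold, 0 alone, 0.0111, 0.66) and T cell effector and cytotoxic (0 of 26 past the threshold, 4 alone, 0.000258, 0.484) ranked higher too. NK cell (0 of 13 past the threshold, 0 alone, 0.00255, 0.484) and macrophage and monocyte (0 of 19 past the threshold, 0 alone, 0.000294, 0.638) ranked higher too. Cytosolic ribosomal proteins (0 of 43 past the threshold, 0 alone, 4.66e-15, 0.484), naive and memory T cell (0 of 24 past the threshold, 2 alone, 0.0188, 0.703) and T cell identity (0 of 17 past the threshold, 0 alone, 0.00034, 0.484) ranked lower. Endothelial (0 of 13 past the threshold, 0 alone, 0.00044, 0.484) ranked lower too. The call of immediate early and dissociation ended with replicate number as a block (0.126). The median of macrophage and monocyte was 1.12, that of interferon response 0.36 and that of ribosomal proteins -0.15. The median of all genes lay 0.10 above 0, and 0.01 after median-of-ratios rescaling. The count was 10 without week 2 replicate 3, 0 with replicate number as a block (adjusted p = 0.0607 for Hspa1a, Hspa1b and Snord14d and 0.0989 for Snord14c, the highest of their alternatives) and 869 with array weights.

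Between weeks 3 and 4 in CD8 T cell libraries, interferon response ranked lower and T cell exhaustion higher as lists. Interferon response genes fell in 21 of 34 and rose in 0 (32 adjusted over the list alone, camera adjusted p = 2.22e-22), with Irgm1 going from 138.9 ± 9.86 to 56.9 ± 4.06 TPM (n = 3 each; log2 -1.27, adjusted p = 0.00509) and Igtp at log2 -1.33. T cell exhaustion rose in 7 of 26 (16 changed adjusted over the list alone, adjusted p = 1.29e-10), with Tigit at log2 1.34 (adjusted p = 0.0097) and Nr4a2 at log2 1.23 (adjusted p = 0.0097). CD4 and regulatory T cell genes rose in 3 of 11 and fell in 1 (7 adjusted over the list alone, adjusted p = 0.000338), with the chemokine receptor Ccr8 at log2 1.97. With an estimated correlation these 3 lists had adjusted p = 0.286, 0.461 and 0.286. Markers of other cells moved in the same libraries. B and plasma cell ranked lower (0 of 12 past the threshold, 2 adjusted over the list alone) and neutrophil higher (0 of 6, 1 adjusted over the list alone), both with adjusted p = 0.0238, and 0.921 and 0.713 with an estimated correlation. The neutrophil call also ended with replicate number as a block (0.303). Cd79a, chosen after its values were seen, was at 17.9 ± 11.9 and 2.07 ± 1.93 TPM. Fibroblast and extracellular matrix genes had medians of -0.99 and -1.25 and did not pass (adjusted p = 0.199 and 0.0821, 0 changed adjusted over either list alone, 0.921 for both with an estimated correlation). In all 11 lists passed. For those not named so far, the values are the members past the threshold, the count adjusted over the list alone, the adjusted p and the adjusted p with an estimated correlation. Oxidative phosphorylation (0 of 37 past the threshold, 0 alone, 1.02e-06, 0.713), cell cycle (0 of 35 past the threshold, 0 alone, 1.39e-05, 0.901) and unfolded protein response (0 of 18 past the threshold, 0 alone, 0.0238, 0.543) ranked higher. T cell effector and cytotoxic (4 of 26 rose, 12 alone, 1.55e-07, 0.517) and NK cell (1 of 13 rose, 3 alone, 0.0135, 0.713) ranked higher too. Naive and memory T cell (2 of 24 fell, 1 rose, 14 alone, 0.00103, 0.785) ranked lower. Nrn1 was among the largest rises (8.20 ± 2.07 to 43.8 ± 8.87 TPM, log2 2.29, adjusted p = 0.00513). Mir7663 was listed at 0 in all 3 week 4 libraries and at 21.2 ± 14.1 TPM at week 3. Pdcd1 rose (log2 1.88, adjusted p = 0.0125), but not without week 3 replicate 3 (0.0516) or week 4 replicate 2 (0.0527) or 3 (0.0561), in a range of 0.00126 to 0.0561 over its alternatives. Gzmb (log2 1.03, adjusted p = 0.251), Tox (log2 0.74, adjusted p = 0.101), Lag3 (log2 0.93, adjusted p = 0.16) and Havcr2 (log2 -0.06, adjusted p = 0.921) did not pass. Tox passed with median-of-ratios rescaling (0.0368), quantile normalization (0.0273) and array weights, in a range of 0.00669 to 0.226. With array weights Gzmb and Lag3 passed as well (0.0211 and 0.0302, in ranges up to 0.498 and 0.384). Of 13350 genes 356 passed, 184 higher and 172 lower at week 4, against a median of all genes of -0.13, or -0.01 after median-of-ratios rescaling. The share of higher genes went from 51.7% to 65.6% with that rescaling and to 61.7% with quantile normalization. The count was 196, 46 and 110 without week 3 replicates 1, 3 and 4, 90, 82 and 630 without week 4 replicates 2, 3 and 4, and 3 with replicate number as a block, where Irgm1, Igtp, Nr4a2 and Nrn1 had an adjusted p of 0.0513, the highest of their alternatives.

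The knockdown tumor cells address the effects of Mogat1, with the limit given above that Mogat1 ran against the labels. Luminal epithelial and milk genes were far higher in the libraries labelled shMogat1. Epcam stood at 29.6 ± 1.17 TPM against 0.692 ± 0.155 in shCTRL (n = 3 each; log2 4.18, SE 0.08, adjusted p = 2.01e-08). The milk protein Csn3 stood at 46.9 ± 0.808 against 0.317 ± 0.219 (log2 5.20) and the luminal keratin Krt8 at 39.7 ± 2.83 against 1.45 ± 0.127 (log2 4.05). Wfdc18 (log2 5.34), the iron carrier Trf (496.6 ± 2.13 against 13.2 ± 0.334, log2 5.13), the haptoglobin gene Hp (log2 4.41), Lcn2 (log2 4.34) and Igfbp5 (log2 3.98) were the other largest rises. The largest falls were Angptl7 (3.53 ± 0.404 against 44.8 ± 1.26 TPM, log2 -3.34), the cartilage proteoglycan Acan (log2 -2.96), the lactate dehydrogenase subunit Ldhb (log2 -2.97), Tmprss11b (log2 -2.82), Fgf7 (log2 -2.70), Hgf (log2 -2.63), Fbln7 (log2 -2.62) and Tnfaip6 (log2 -2.59). Fibroblast genes as a list rose in 10 of 18 and fell in 5 (15 adjusted over the list alone, adjusted p = 0.676, and 0.853 with an estimated correlation). Set beside the tumor time course as a description, both arms held little Epcam and much Vim, a filament protein of mesenchymal cells. Epcam averaged 305.4 TPM at week 2 and 528.9 at week 4. Vim averaged 8511 TPM in shCTRL and 6242 in shMogat1, against 4298 at week 2 and 710.4 at week 4. Whether the arms differ in their share of epithelial cells or within those cells was not tested.

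Luminal epithelial genes rose in 16 of 20 and fell in 2 (18 adjusted over the list alone, camera adjusted p = 1.22e-05), Krt18 from 203.0 ± 8.27 to 860.3 ± 22.8 TPM. Milk and secretory differentiation genes rose in 7 of 8 (7 adjusted over the list alone, adjusted p = 0.000204). Basal and myoepithelial genes went both ways, with 5 of 11 higher and 5 lower (11 adjusted over the list alone, adjusted p = 0.993, also with an estimated correlation) and a median of -0.17 under a mean of 0.80. Interferon response genes rose in 32 of 34 and fell in 1 (33 adjusted over the list alone, adjusted p = 4.11e-08): Zbp1, a sensor of nucleic acids, rose by log2 1.46 and Gbp2 fell by log2 0.44. Macrophage and monocyte genes rose in 20 of 20 (20 adjusted over the list alone, adjusted p = 1.45e-07), such as Ctss and C1qa (log2 1.23 for both). With an estimated correlation, adjusted p = 0.101 for the luminal, milk, interferon and macrophage lists. T cell identity (10 of 11 rose, 10 adjusted over the list alone, adjusted p = 0.00962), T cell effector and cytotoxic (10 of 11 rose, 10 adjusted over the list alone, adjusted p = 0.00418) and dendritic cell markers (7 of 8 rose, 7 adjusted over the list alone, adjusted p = 0.0465) moved with them, at 0.171, 0.156 and 0.261 with an estimated correlation. The dendritic cell call also ended with replicate number as a block (0.0562). Ptprc stood at 11.5 ± 0.434 TPM against 4.06 ± 0.211. Cytosolic ribosomal proteins fell in 31 of 43 and rose in 0 (33 adjusted over the list alone, adjusted p = 4.19e-10, and 0.181 with an estimated correlation), by a median of log2 0.10, with Rpl13 at log2 -0.49. The count depended on scaling: 42 fell after median-of-ratios rescaling, and 10 fell and 3 rose after quantile normalization, with a median of -0.01. Cell cycle genes rose in 13 of 35 and fell in 6, with a median of 0.03 and a test pointing down (adjusted p = 0.993, also with an estimated correlation), and median-of-ratios rescaling turned them to 7 higher and 12 lower. Cd274 rose (log2 0.63, adjusted p = 0.000175), as did Plin2 and Cpt1a (log2 0.27 for both, adjusted p = 0.000238 and 0.000653) and Mki67 (log2 0.14, adjusted p = 0.00714). The Mki67 call ended after median-of-ratios rescaling (0.0939, in a range from 0.00499). Dgat1 (log2 -0.17, adjusted p = 0.0258), B2m (log2 -0.07, 0.0429) and Cxcl10 (log2 0.17, 0.0366) passed less firmly. The Dgat1 call ended without shCTRL replicate 2 (0.0839) or 4 (0.058) or shMogat1 replicate 1 (0.0675) or 2 (0.0741). That of B2m ended without any library but shMogat1 replicate 2 (0.0562 to 0.124) and that of Cxcl10 without any but shCTRL replicate 2 (0.0555 to 0.113). Over all alternatives p ran from 0.00413 to 0.0839, 0.00355 to 0.311 and 0.000313 to 0.176.

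Of 12936 genes 7052 passed, 4479 higher and 2573 lower in the libraries labelled shMogat1, and 752 changed at least 2-fold; median-of-ratios rescaling brought the share of higher genes from 63.5% to 49.1%. Replicates of an arm differed little, with a median squared difference of 2.41 to 2.53 times the counting noise per pair of libraries against 5.32 to 28.4 in the tumor time course, so many small differences pass.

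**Figure D3:**
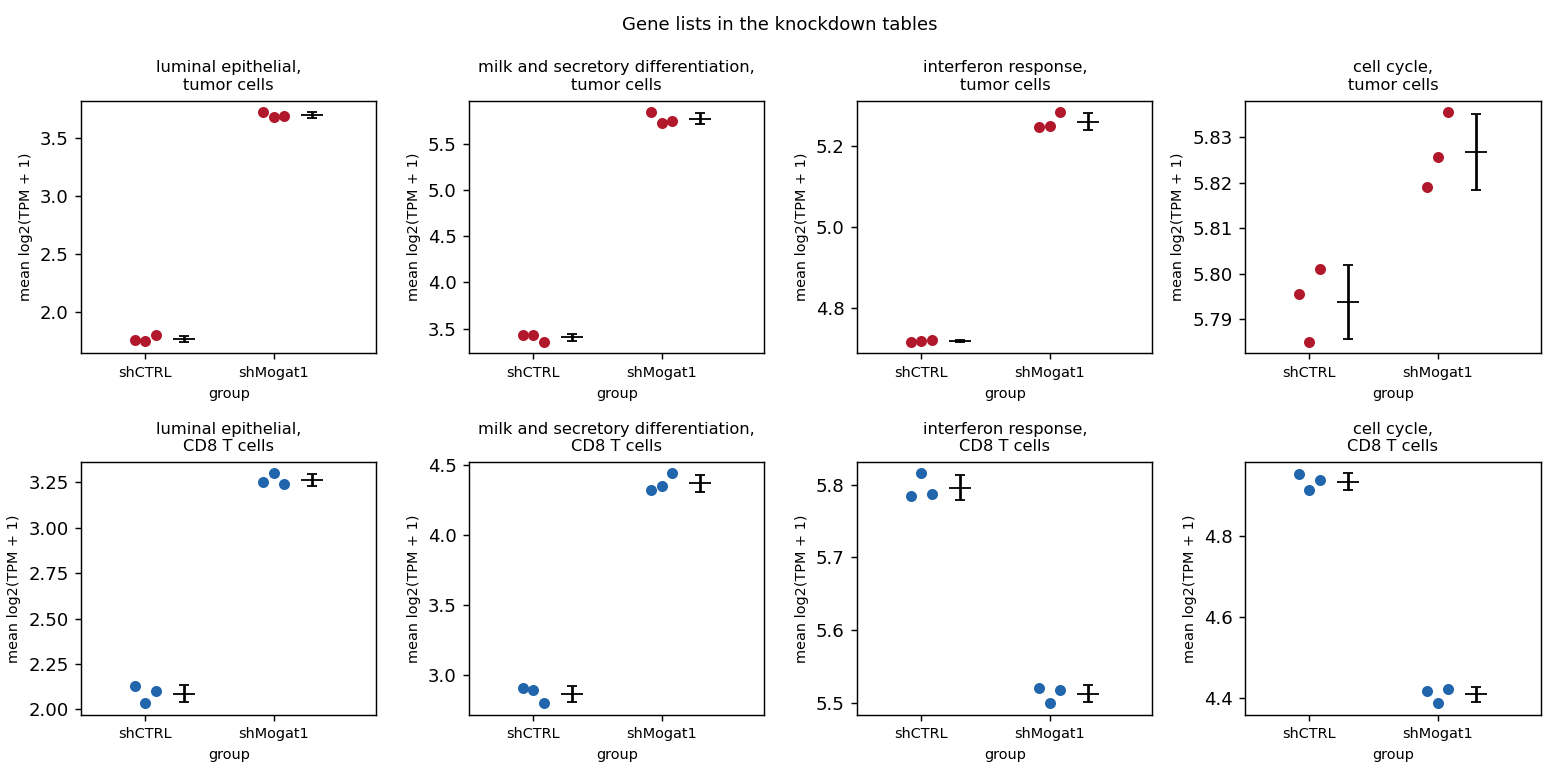
Mean log2(TPM + 1) of the luminal epithelial, milk and secretory differentiation, interferon response and cell cycle lists per knockdown library, by the labels shCTRL and shMogat1, in tumor cells and CD8 T cells (points, with bars for mean and SD; axes differ between panels and do not start at 0). In tumor cells the luminal list averaged 1.77 in shCTRL and 3.70 in shMogat1, and in CD8 T cells 2.09 and 3.26; the cell cycle list in tumor cells turned direction with rescaling.

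CD8 T cells of the knockdown set address whether T cells differ between the tumors. Several granzymes were much lower in the libraries labelled shMogat1: Gzmd at 0.320 ± 0.299 against 24.8 ± 1.31 TPM in shCTRL (n = 3 each; log2 -4.31, SE 0.16, adjusted p = 1.41e-06) and Gzmf at 1.19 ± 0.667 against 35.3 ± 0.846 (log2 -4.09). Gzme and Gzmg were listed at 0 in all 3 shMogat1 libraries and at 14.6 ± 1.61 and 5.06 ± 1.43 TPM in shCTRL. Gzmb (log2 -0.70, adjusted p = 4.00e-06), Prf1 (log2 -0.71, adjusted p = 1.58e-05), Havcr2 (log2 -0.66, adjusted p = 2.39e-05), Lag3 (log2 -0.76, adjusted p = 4.03e-05) and Mki67 (log2 -0.80, adjusted p = 1.46e-05) fell by less. Pdcd1 rose from 145.3 ± 2.62 to 194.1 ± 4.34 TPM (log2 0.42, adjusted p = 4.22e-05), as did Tox (log2 0.28, adjusted p = 0.0022), Tcf7 (log2 0.13, adjusted p = 0.00507, but 0.0955 with replicate number as a block, in a range from 0.00108) and Ifng (log2 0.26, adjusted p = 0.00135), and Cd8a was at log2 -0.03 (adjusted p = 0.521). The largest rises were Lcn2 (4.20 ± 2.55 to 178.5 ± 5.41 TPM, log2 5.21), Wfdc18 (log2 4.64), Csn3 (log2 4.49), Igfbp5 (log2 4.05), Krt8 (log2 3.43), Krt14 (log2 3.15) and the collagens Col9a1 (log2 3.03) and Col2a1 (log2 2.89). Other large falls were Angptl7 (log2 -2.85), the deiodinase Dio2 (log2 -2.82), Fcrl6 (log2 -2.62) and Notum, an inhibitor of Wnt signalling (log2 -2.57).

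Cell cycle genes fell in 32 of 35 and rose in 0 (33 changed adjusted over the list alone, camera adjusted p = 3.97e-10, and 0.0855 with an estimated correlation), with Ccnb2 at log2 -0.88 and Top2a at log2 -0.75. Naive and memory T cell genes rose in 18 of 24 and fell in 4 (23 adjusted over the list alone, adjusted p = 6.01e-06, and 0.108 with an estimated correlation), such as S1pr1, a receptor for leaving tissues (log2 0.67), and Ccr7, a homing receptor of lymph nodes (log2 0.50). T cell effector and cytotoxic genes fell in 15 of 28 and rose in 4 (19 adjusted over the list alone, adjusted p = 0.0229, and 0.161 with an estimated correlation). Interferon response genes fell in 23 of 34 and rose in 4 (28 adjusted over the list alone, adjusted p = 0.000383, and 0.151 with an estimated correlation), among them Mx1 (log2 -0.95) and Usp18 (56.9 to 27.9 TPM). T cell exhaustion rose in 6 of 25 and fell in 9 (15 adjusted over the list alone, adjusted p = 0.72, and 0.838 with an estimated correlation). T cell identity rose in 6 of 17 and fell in 1 (7 adjusted over the list alone, adjusted p = 0.0225, and 0.354 with an estimated correlation). Markers of other cells moved in both directions. Luminal epithelial genes rose in 14 of 20 and fell in 3 (17 adjusted over the list alone, adjusted p = 3.33e-06, and 0.0855 with an estimated correlation), Epcam from 3.87 ± 0.931 to 29.4 ± 1.03 TPM. Fibroblast genes fell in 12 of 18 and rose in 1 (14 adjusted over the list alone, adjusted p = 6.01e-06, and 0.151 with an estimated correlation), such as Dcn (log2 -2.28) and Pdgfra (log2 -1.61). Extracellular matrix genes moved likewise (18 of 28 fell, 2 rose, 22 adjusted over the list alone, adjusted p = 3.33e-06, and 0.23 with an estimated correlation), such as Mmp2 (log2 -1.95). Dendritic cell genes fell in 9 of 14 and rose in 1 (10 adjusted over the list alone, adjusted p = 0.00369, and 0.151 with an estimated correlation), including Siglech of plasmacytoid dendritic cells (log2 -2.38) and Irf8 (log2 -1.19). In all 16 lists passed. For those not named so far, the values are the members past the threshold, the count adjusted over the list alone, the adjusted p and the adjusted p with an estimated correlation. Fatty acid synthesis (8 of 20 rose, 2 fell, 10 alone, 0.0476, 0.401), milk and secretory differentiation (6 of 10 rose, 6 alone, 1.25e-05, 0.0906) and cytosolic ribosomal proteins (9 of 43 rose, 1 fell, 10 alone, 0.0131, 0.624) ranked higher. Glycolysis (12 of 22 fell, 3 rose, 16 alone, 0.0327, 0.3), oxidative phosphorylation (16 of 37 fell, 16 alone, 0.00967, 0.479) and MHC class I presentation (10 of 14 fell, 1 rose, 11 alone, 0.0283, 0.479) ranked lower. Immediate early and dissociation (16 of 25 fell, 6 rose, 22 alone, 0.00436, 0.161) ranked lower too. With replicate number as a block the calls of fatty acid synthesis (0.0534), glycolysis (0.0908) and ribosomal proteins (0.231) ended. Beside all of these, the tumor RNA share from Y-linked genes ran from 18.0% to 21.6% in shCTRL and from 9.29% to 10.4% in shMogat1 (n = 3 each), and Vim, abundant in the tumor cells, stood at 2382 ± 94.9 and 1288 ± 21.6 TPM.

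Of 13742 genes 5878 passed, 2279 higher and 3599 lower in the libraries labelled shMogat1, and 477 changed at least 2-fold. The split did not hold with rescaling: the share of higher genes went from 38.8% to 49.6% (median-of-ratios) and 54.0% (quantile). Among genes with a lower mean in the tumor table, a restriction chosen after seeing the data, 2368 passed and the split turned to 1657 higher and 711 lower. The lower tumor RNA share of the libraries labelled shMogat1 would move such genes in the same direction, and its part was not tested. Replicates of an arm differed little here as well, with a median squared difference of 2.42 to 3.62 times the counting noise per pair. In the CD8 T cell time course it was 8.27 to 14.7. No label says whether these replicates came from separate animals, so the p-values may measure technical spread.

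Set side by side, the time course and the knockdown tested 12624 tumor cell genes in common, a description of calls made within separately scaled tables. Of the genes higher at week 4 than at week 2, 485 were lower and 1577 higher in the libraries labelled shMogat1, where 735.5 and 1290 would be shared if the calls were independent. Of those lower at week 4, 695 were lower and 724 higher under that label, with 445.8 and 782.1 for independent calls. Mogat1 itself was among the week 4 rises, while in the knockdown table it missed the filter.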

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

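The tests of other splits, both tests of Mogat1 in the knockdown tumor cells, the test of tumor cell carry-over and the test of interferon genes in CD8 T cells were chosen only after the results were seen.

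In 188 groups of 4 libraries, a gap test asked whether 1 library lay far from the others. It picked out 8, against 9.4 that a chance rate of about 1 in 20 groups would give, so the 8 together are no more than chance gives. In tumor week 3, replicate 4 had the highest mean of the lipolysis and lipid droplet list (4.90) and of the milk and secretory differentiation list (4.96), and replicate 1 the highest of the ribosomal protein list (10.52). In tumor week 4, replicate 4 was highest for Zfp750 (54.6 TPM), Kit (113.5 TPM) and Nppb (0.195 TPM) and lowest for Cma1 (0 TPM), and replicate 2 was highest for Prl2c2 (0.181 TPM).

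In 16 results, tumor cell and CD8 T cell libraries moved in opposite directions. Within each cell type, the libraries of the groups compared did not overlap, and the difference between cell types was not tested. Cd8a and the T cell and NK cell lists are markers of immune cells, so in tumor libraries their change need not be one of tumor cells. Over time, 31 results were compared. The change from week 2 to week 4 in CD8 T cells minus that in tumor cells was 1.31 log2 for immune checkpoint ligands, 1.79 for T cell exhaustion, 2.22 for T cell effector and cytotoxic, 1.64 for CD4 and regulatory T cell, 2.56 for NK cell and 3.10 for Cd8a. In the knockdown set, 29 results were compared. The difference between the libraries labelled shMogat1 and shCTRL in CD8 T cells minus that in tumor cells was -0.82 for interferon response, -1.36 for T cell effector and cytotoxic, -1.49 for dendritic cell and -0.36 for glycolysis. It was -0.34 for MHC class I presentation, -0.56 for cell cycle, -0.68 for extracellular matrix, -1.08 for fibroblast, -0.94 for Mki67 and -1.70 for Irf8. In the CD8 T cell libraries, the tumor RNA share averaged 20.2% in shCTRL and was at most 10.4% in shMogat1. Vim, abundant in the tumor cells, stood at 2382 and 1288 TPM there. Lower fibroblast and extracellular matrix genes in these libraries therefore need not be a change of T cells. The part of tumor RNA in these differences was not tested. For cell cycle, glycolysis and extracellular matrix, the median in tumor cells turned from 0.03, 0.05 and 0.05 to -0.04, -0.02 and -0.02 with median-of-ratios rescaling.

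For tumor cells over time, each real split gave more genes than any of the other 34 of 35 splits. A share of 1 in 35 is the smallest that these splits can reach. The other splits mix the weeks, the contrasts share libraries, and no label says whether replicates came from separate animals. The ranks are therefore a description and do not exclude chance. The counts were 6843 for week 4 against week 2 (highest other 1), 3560 for week 3 against week 2 (highest other 317) and 2026 for week 4 against week 3 (highest other 1). The 10 splits of the other comparisons are too few for a share under 0.05. Their real counts and highest others were 2335 and 0, 6 and 1, and 356 and 1 for CD8 T cells (week 4 against 2, 3 against 2 and 4 against 3). For shMogat1 against shCTRL they were 7052 and 1 in tumor cells and 5878 and 0 in CD8 T cells.

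Mogat1 was higher in the tumor libraries labelled shMogat1, against the label. RNA of epithelial cells that hold Mogat1 is a candidate explanation, since the same libraries held far more Epcam: Mogat1 stood at 1.47 ± 0.878 per 100 TPM of Epcam, against 0.701 ± 0.299 in tumor cells of week 2 and 7.04 ± 0.501 at week 4. For shCTRL and shMogat1 labels swapped in the tumor cell table no test decided: more Mogat1 in the shMogat1 library in 9 of 9 pairs only restates the observation. A swap cannot be told apart from the first explanation, because Epcam separates the same arms. The CD8 T cell table gives the same differences under the same labels (Epcam 29.4 ± 1.03 and 3.87 ± 0.931 TPM, Angptl7 log2 -2.85 there and -3.34 in tumor cells). A swap in the tumor table alone would set the tables against each other if both came from the same tumors, which no label states, and a swap in both would not. With 2 to 12 reads per tumor library labelled shMogat1 and 0 in those labelled shCTRL, the knockdown itself stayed untested.

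Epithelial genes were higher in the CD8 T cell libraries labelled shMogat1. Carry-over of cells with the mean profile of the tumor cell libraries would bring an excess at or under the tumor RNA share, at most 10.4%. It would be lower for genes that the shCTRL tumor libraries also held, since the share averaged 20.2% in the shCTRL CD8 T cell libraries. The median excess over 24 risen members was 81.0% of that in the tumor table (first quartile 66.4%). Over all 33 tested members with more TPM in the shMogat1 arm of the tumor table, risen or not, it was 69.7% (first quartile 30.5%), a check made after the value was seen. This argues against carry-over as the source of most members, though 7 of the 33 lay at or under that share, Krt18 (9.66%) among them. These 7 include Cdh1 (-43.1%), Gata3 (-33.5%), Mylk (-3.16%) and Xdh (-0.255%), which were lower, not higher, in the CD8 T cell libraries labelled shMogat1. Epithelial cells unlike the mean of the tumor cell libraries stay open as a source. Of the risen members, 100% (23 of 23) lay within 4-fold of the level predicted from the Epcam share and the week 2 tumor profile, but they were picked for their rise, and the prediction had not named a week. Of all 38 tested members other than Epcam 26 did, a count made after the value was seen. Among those chosen from it, Ly6d (1.54 TPM more against 31.7 predicted), Glycam1 (0.891 against 19.8) and Mfge8 (5.09 against 40.9) stayed far lower, so the test decides nothing. Whether such cells differed between the tumors was not tested.

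Interferon response genes were lower in tumor cells at week 4 than at week 2. Less RNA of immune cells could lower them, and the fall was 88.5 times that predicted from Ptprc with the profile of CD8 T cells (quartiles 39.2 and 160). This bound was wrong, because the immune cells of the tumor libraries were of another kind: Lyz2 per Ptprc was 15.8 in tumor week 2 and 0.102 in CD8 week 2, 154 times apart, a check chosen after the value was seen. Lower interferon exposure of tumor and T cells alike is in line with 18 members lower at week 4 in CD8 T cells and 0 higher. Against a shared decline from week 2 on, the list mean was higher in CD8 T cells at week 3 (5.41) than at week 2 (5.03), and both explanations stay open.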

How the results depend on the processing

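Restricting tests to genes with a lower mean in the table of the other cell type was chosen only after the results were seen. Where a count moved, the cause was not tested, except that a 2-fold minimum lowers counts by construction.

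A 2-fold minimum gave 2260, 670 and 712 genes in tumor cells (week 4 against 2, 3 against 2, 4 against 3), 974 and 194 in CD8 T cells (4 against 2, 4 against 3), and 752 and 477 for the knockdown tumor cells and CD8 T cells. Array weights, whose estimation stopped before convergence in 3 fits, gave 4614 in tumor cells for week 4 against 3, and 5910, 869 and 3661 in CD8 T cells (4 against 2, 3 against 2, 4 against 3). Replicate number as a block gave 1422, 0 and 3 in CD8 T cells in that order. Fitting only the 2 weeks compared gave 1637 (week 3 against 2) and 3857 (4 against 3) in tumor cells and 1356 in CD8 T cells (4 against 2). For week 4 against 3 in CD8 T cells, no filter gave 234 and quantile normalization 605. The added restriction gave 4351 and 1494 (week 4 against 2, tumor cells and CD8 T cells) and 4242 and 2368 (knockdown).

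Leaving out 1 library gave 5278 to 7765 genes (tumor, week 4 against 2), 1371 to 5751 (week 3 against 2, without week 2 replicates 2 and 1) and 1251 to 3580 (week 4 against 3, without week 3 replicate 3 and week 2 replicate 1). In CD8 T cells it gave 928 to 3115 (without week 2 replicates 2 and 3), 5 to 10 (the latter without week 2 replicate 3) and 46 to 630 (without week 3 replicate 3 and week 4 replicate 4). In the knockdown it gave 5842 to 6369 and 4620 to 5465. The knockdown value of Mogat1 was 2.27 and 0.12 with pseudocounts of 0.1 and 5, 0.18 with quantile normalization, no longer under 0.05, and 0.41 to 0.66 without 1 library. Its rise over time kept its call under every alternative (3.33 to 3.97, 1.01 to 1.64 and 2.17 to 2.48 without 1 library).

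Of 4691 values for 256 gene results, 4481 kept their call, 178 lost it, 32 gained it and 0 reversed. Of 128 list calls, 0 held with an estimated correlation, 62 with fry and 119 with the block, and 0 reversed. Within a time course table, correlations of same-number libraries ran from -0.26 to 0.23 in tumor cells and from -0.24 to 0.43 in CD8 T cells. Those of other numbers ran from -0.36 to 0.32 and from -0.43 to 0.45. Correlations between tumor cell and CD8 T cell libraries were not run.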

Other observations

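Xist, the RNA that silences an X chromosome in female cells, was at 5.76 TPM in the tumor libraries labelled shMogat1 and 1.98 in those labelled shCTRL (n = 3 each). The Y-linked Ddx3y was at 100.2 and 127.4 TPM in the same order. The other Y-linked genes used for the tumor RNA share were not lower under the label shMogat1. Eif2s3y was at 50.04 and 49.51 TPM, Kdm5d at 13.3 and 12.4 and Uty at 12.6 and 11.6. In the time course, week 3 replicate 3 had by far the lowest Xist of its group in tumor cells (0.697 TPM) and in CD8 T cells (7.63 TPM). The other week 3 libraries held 12.8 to 29.9 TPM in tumor cells and 217.8 and 194.5 TPM in CD8 T cells. No label says whether the tumor cell and CD8 T cell libraries of that number came from the same animal. Vim, a filament protein of mesenchymal cells, fell in tumor cells from week 2 to week 4 (4298 to 710.4 TPM), with 2014 TPM at week 3. The macrophage lysozyme Lyz2 was at 880.5, 395.4 and 293.1 TPM in the same groups. Across all genes tested in both tables, the log2 changes from week 2 to week 4 and between shMogat1 and shCTRL had a Pearson correlation of 0.115 and a Spearman correlation of 0.134, over genes, which are not independent replicates.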
